A study of Homo sapiens with 6 samples.

How the data were processed

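RNA from 6 samples, 3 with a control shRNA and 3 with an shRNA against SHCBP1, was hybridised to Affymetrix PrimeView arrays, 1 sample per array. Groups and replicate numbers come from the sample titles. The labels describe biotin-labelled cRNA made from total RNA, and name the cells as TPC-1 in the titles and DLD1 in the extraction text.

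The deposited table holds 1 log2 value per probe set and array, which the authors made with RMA (background correction, quantile normalization and summarisation of probes), per the submitters' processing notes. Its log base is not stated, and log2 was taken because it is the scale of RMA. Each probe set's median over the 6 arrays is 0 in the table, so the values were centred per probe set before they were deposited. That step, the RMA software and its version are not given in the sources used here. Because of the centring no brightness or background level is left, and a value only compares arrays. RMA's quantile step gives all arrays nearly the same distribution, so a shift of all transcripts in one direction would be removed.

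Of 49395 probe sets in the table, 102 are Affymetrix controls, 44988 have 1 gene symbol in the platform annotation, 1832 have several and 2473 are unnamed here. Of those with 1 symbol, 44961 matched a gene of the RefSeq table (assembly GRCh38.p14) by Entrez number, 27 did not, and 0 symbols needed an update. That table was used for names only. Probe sets with several symbols or none were left out of the gene tests, and 640 and 765 of them passed the threshold on their own.

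The design fixed a filter on dim genes and the brightest probe set for each gene. Neither could be applied to centred values, so each of 18132 genes was represented by the mean of all its probe sets that name only that gene, with no filter. More than 1 probe set was averaged for 11734 genes, and 482 genes had probe sets past the threshold in both directions.

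Differences (SHCBP1 shRNA minus control shRNA) were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, unpaired, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A size of 1 on the log2 scale marked a 2-fold change. Errors are the moderated standard errors of limma, and those of control probe sets are standard errors of the difference of group means. The 39 gene lists, with 869 distinct genes of which 816 were tested, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the lists. Counts "adjusted over the list alone" apply the adjustment to the members of that list only. The adjusted p-values of limma model the spread between 3 arrays per group.

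The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names SHCBP1, the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, and up to 4 members with the largest changes past the threshold per list (up to 2 tested members where none passed). Genes named outside this rule are marked as chosen after their values were seen.

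The scripts were tested on simulated data for this comparison with 18132 genes. Of genes simulated with a change of 0.25, 0.5 and 1 on the log2 scale, 49.3%, 86.6% and 97% were recovered, and 5 of 160 calls were false. The 1 list simulated with a shift was the only one called of 39. The simulated noise was independent between genes and few genes were changed. In the data the estimated correlation within a list reached 0.192, so the simulation does not show how often camera calls unshifted lists there. No array repeated another: differences between arrays of one group had an SD of 0.105 to 0.111, against 0.302 to 0.309 between groups.

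The alternatives fixed with the design were repeated quantile normalization, centring of arrays, array weights, the replicate number as a block, leaving out each array, each probe set on its own, and the other set tests. Alternatives added after seeing the data were robust moderation, scaling to the poly-A spike-in controls, only plain _at probe sets, and leaving out _s_at and _x_at probe sets, which Affymetrix names for probes shared between transcripts or genes.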

Results

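Gene expression was measured on 6 Affymetrix PrimeView arrays, 3 from cells given a control short hairpin RNA (shRNA) and 3 from cells given an shRNA against SHCBP1, both carried by lentivirus. The labels name the cells as TPC-1, an established human papillary thyroid carcinoma line, while the extraction text of the same labels names DLD1, a colorectal carcinoma line. The comparison asks which genes differ when SHCBP1, a partner of the adaptor protein SHC1 that also takes part in cytokinesis, is knocked down. No sample title names another shRNA against SHCBP1 or a rescue, so loss of SHCBP1 and other effects of the shRNA cannot be told apart. The labels speak of independent samples but not of separate cultures, so p-values here measure the spread between these samples, which may be technical. The deposited log2 values are centred on each probe set's median over the 6 arrays, so they give changes between arrays and no expression levels. The number of arrays, 3 per group, limits the precision.

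SHCBP1 itself (Entrez Gene 79801) fell 2.91-fold in the SHCBP1 shRNA arrays, a log2 fold change of -1.54 ± 0.06 (SE, n = 3 arrays per group, 95% confidence interval -1.68 to -1.40). Its centred log2 values were 0.72, 0.76 and 0.71 in the control arrays and -0.95, -0.76 and -0.72 in the SHCBP1 shRNA arrays. Both of its probe sets fell, by 1.61 and by 1.48 on the log2 scale. The drop passed limma's moderated test (Benjamini-Hochberg adjusted p = 1.87e-06), and 26 genes fell further than SHCBP1. Among its known partners, both chosen after their values were seen, SHC1 fell with a log2 fold change of -0.18 ± 0.04 (SE) and the centralspindlin subunit RACGAP1 rose by 0.27 ± 0.03 (SE).

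The genes that rose furthest in the SHCBP1 shRNA arrays included 3 that are known to respond to the YAP co-activator: ANKRD1 (5.57-fold), CCN1 (4.15-fold) and CCN2 (3.80-fold). The galectin gene LGALS1 rose 4.24-fold, the histone gene H2AC6 4.56-fold, the G-protein regulator RGS2 3.73-fold and the homeobox gene MSX1 3.65-fold. The value of H2AC6 rests on 1 probe set, whose name ends in _s_at. Those of ANKRD1, LGALS1, RGS2 and MSX1 rest on 1 probe set each too. AQP11, KITLG, CD163, PCP4 and KCNJ8 rose between 2.85-fold and 3.05-fold, and the 4 probe sets of KITLG rose by 0.85 to 2.21 on the log2 scale. CD163, PCP4 and KCNJ8 have 1 probe set each. Standard errors of these 12 rises ran from 0.03 for KITLG to 0.12 for CD163 on the log2 scale.

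The cytokine gene IL33 fell furthest, 6.01-fold (log2 fold change -2.59 ± 0.03, SE), followed by the calcium-binding protein gene S100P (5.28-fold), the proteasome assembly chaperone gene PSMD10 (4.63-fold) and the trefoil peptide gene TFF1 (4.23-fold). PSAT1 of serine synthesis fell 3.96-fold, UAP1 and GNPNAT1 of UDP-N-acetylglucosamine synthesis 3.88-fold and 3.52-fold, and PAICS of purine synthesis 3.53-fold. DDIT4, an inhibitor of mTORC1 signalling, fell 3.92-fold, the translation inhibitor gene PDCD4 3.72-fold, APLP2 3.63-fold and TXNIP, which restrains glucose uptake, 3.62-fold. Of these falls, S100P, TFF1, DDIT4 and UAP1 rest on 1 probe set each. The rule that chose these 24 genes required that all 3 values of one group lay above all 3 of the other and that limma's test was passed. Their Benjamini-Hochberg adjusted p-values from limma ran from 5.89e-08 (IL33) to 4.17e-05 (CD163).

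**Figure D1:**
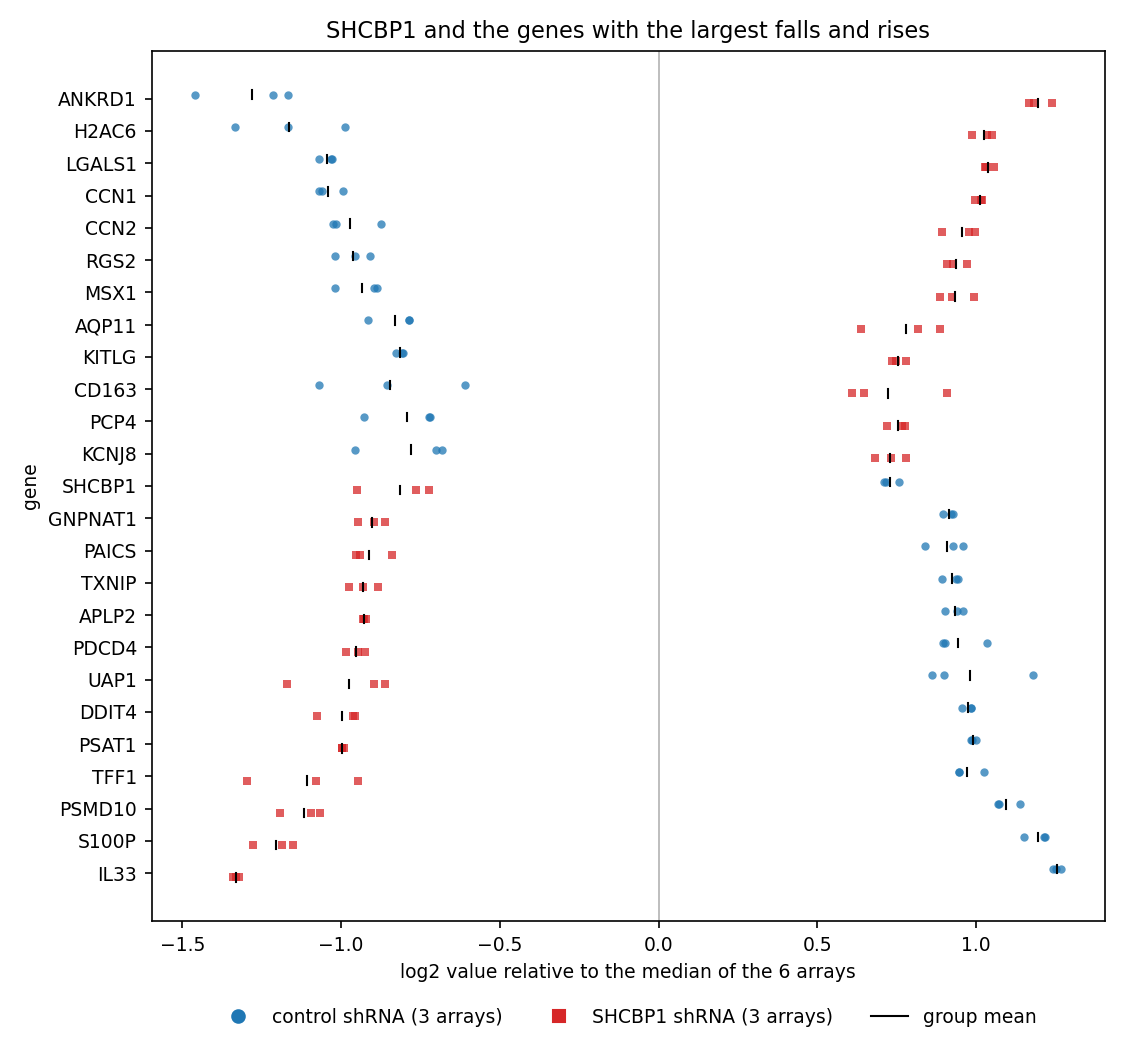
Centred log2 values of SHCBP1 and of the 12 genes with the largest rises and the 12 with the largest falls, 1 point per array (control shRNA, circles; SHCBP1 shRNA, squares), with a black mark at each group mean. The groups do not overlap for any gene shown, which the rule for choosing genes required of all but SHCBP1. IL33 runs from a control mean of 1.25 to a mean of -1.33 with SHCBP1 shRNA.

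Of 18132 genes tested, 7440 (41%) passed limma's test at an adjusted p under 0.05, with 3992 higher and 3448 lower in the SHCBP1 shRNA arrays. Most of these changes were small: the median size was 0.29 on the log2 scale, and 5951 of the 7440 (80%) were under 0.5. A change of at least 2-fold was seen for 221 genes, of which 57 rose and 164 fell. In 9067 genes (50%) the groups did not overlap, against the 10% that chance gives for 3 arrays against 3. Repeating the quantile normalization gave 93 rises and 119 falls of at least 2-fold, but on centred values that step evens the tails by construction.

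Control probe sets differed between the groups too. Transcripts of the poly-A spike-in controls, added before labelling, were higher in the SHCBP1 shRNA arrays by 0.43 ± 0.04 log2 (SE), and the 5′ probe set for 28S ribosomal RNA was higher by 2.80 ± 0.03 log2 (SE). The ratio of 3′ to 5′ signal, a sign of RNA degradation, moved by -0.08 log2 for ACTB and -0.01 log2 for GAPDH. Scaling to the spike-in controls, an alternative chosen after seeing the data, shifts every gene by -0.43 log2 and gives 441 genes higher and 16268 lower (17 and 677 of at least 2-fold). All changes reported here are therefore relative to the other genes on the arrays, and 12 of the 59 named genes that rose did so by less than that shift.

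**Figure D2:**
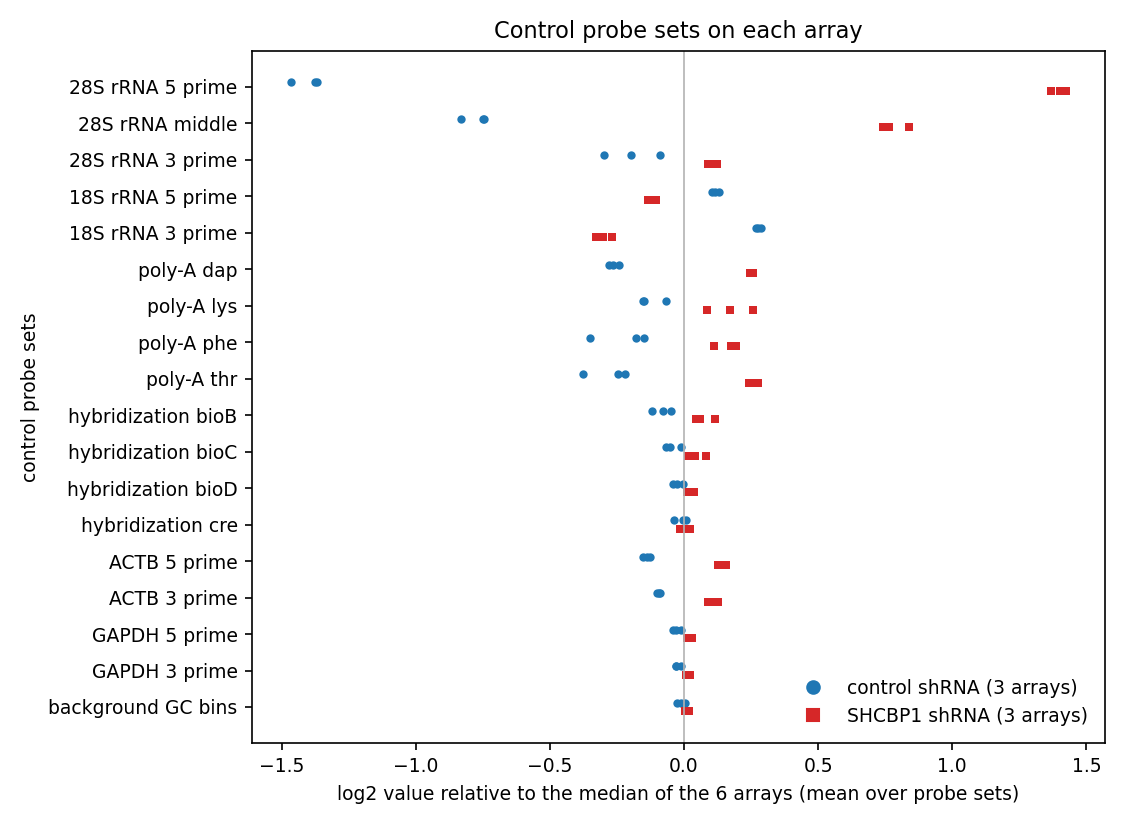
Centred log2 values of the control probe sets on each array (control shRNA, circles; SHCBP1 shRNA, squares), averaged over the probe sets of each control. The 28S 5′ probe set shows the widest gap, 2.80 log2, the 4 poly-A controls are higher with SHCBP1 shRNA by 0.30 to 0.54, and the cre hybridization control differs by 0.02.

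Genes of the amino acid response driven by the transcription factor ATF4 fell together. Of 25 tested, 20 fell and 1 rose (21 and 1 adjusted over the list alone), with a median log2 fold change of -0.71. PSAT1 fell by 1.99 on the log2 scale, the mitochondrial enzyme gene PCK2 by 1.62, the cystine transporter gene SLC7A11 by 1.20 and the asparagine synthetase gene ASNS by 1.15. The list was lower than other genes by limma's camera test with Benjamini-Hochberg adjustment (adjusted p = 2.66e-10, and adjusted p = 0.173 with an estimated correlation).

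Genes of the unfolded protein response were also lower: 11 of 18 fell and 1 rose, the same counts adjusted over the list alone, with a median of -0.44. The endoplasmic reticulum chaperone genes CALR and HSPA5 fell by 1.27 and 1.01 on the log2 scale, the co-chaperone gene DNAJC3 by 0.89 and the transcription factor gene XBP1 by 0.72. The camera test with Benjamini-Hochberg adjustment gave an adjusted p = 6.14e-06, and adjusted p = 0.177 with an estimated correlation.

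Feedback genes of the MAPK pathway, which are induced by ERK signalling, fell in 16 of 22 cases and rose in 1, with the same counts adjusted over the list alone. The phosphatase gene DUSP5 fell by 1.70 on the log2 scale, PHLDA1 by 1.59, the transcription factor gene ETV5 by 1.45 and IER3 by 1.24. The median was -0.29 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.64e-06, and adjusted p = 0.173 with an estimated correlation). Among genes of SHC and growth factor receptors, 7 of 24 fell and 2 rose (8 and 4 adjusted over the list alone). The phosphatase gene PTPN11 fell by 1.05 and EGFR by 0.79, although their probe sets ranged from -2.02 to 0.07 and from -1.67 to 0.10. GAB1 rose by 0.28, with probe sets from -0.07 to 0.68, and INSR fell by 0.24. The list did not pass limma's camera test with Benjamini-Hochberg adjustment (adjusted p = 0.29).

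Epithelial junction genes were lower, with 16 of 23 falling and 1 rising, the same adjusted over the list alone. The keratin gene KRT8 fell by 0.84 on the log2 scale and the tight junction genes OCLN and CLDN7 by 0.75 and 0.62. CDS1, with the largest fall in the list (1.31), encodes an enzyme of phospholipid synthesis, not a junction protein. The median was -0.18 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.92e-06, and adjusted p = 0.237 with an estimated correlation). Mesenchymal transition genes showed 2 rises and 2 falls among 18 (1 and 1 adjusted over the list alone). S100A4 rose by 0.38, SNAI2 rose by 0.35, SNAI1 fell by 0.26 and TCF4 fell by 0.24.

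Matrix-degrading proteases and their inhibitors were lower in 14 of 26 cases and higher in 2 (15 and 2 adjusted over the list alone), with a median of -0.12. The surface proteases ADAM9 and ADAM17, which are known mainly for shedding membrane proteins, fell by 1.28 and 0.82 on the log2 scale. The lysosomal protease gene CTSB fell by 0.93, and SERPINE2, which encodes a protease inhibitor, by 0.89. Probe sets ranged from -1.32 to -0.04 for ADAM17 and from -1.34 to 0.08 for SERPINE2. The camera test with Benjamini-Hochberg adjustment gave adjusted p = 0.000853, and adjusted p = 0.173 with an estimated correlation.

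Genes of DNA replication rose as a group, with 21 of 31 higher and 4 lower, the same adjusted over the list alone. The replisome genes GINS2 and MCM6 rose by 0.98 and 0.89 on the log2 scale and E2F2 by 0.72, whereas the origin-licensing gene CDC6 fell by 0.80. The median was 0.30 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000148, and adjusted p = 0.311 with an estimated correlation). Histone genes rose in 9 of 16 cases and fell in 1 (9 and 2 adjusted over the list alone), with a median of 0.17. H2AC6 rose by 2.19, H2BC12 by 1.31 and H2BC5 by 0.87, and the linker histone gene H1-4 fell by 1.53. Camera with Benjamini-Hochberg adjustment gave adjusted p = 0.00665, and adjusted p = 0.394 with an estimated correlation. Histone genes have near-identical copies and their values are uncertain: without probe sets ending in _s_at or _x_at the list did not pass (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.554), and the 2 probe sets of H2BC12 gave 0.31 and 2.31. Spike-in scaling lowers every gene alike and puts the medians of all 39 lists below 0, these included (-0.13 for replication and -0.26 for histones), so both rises are relative to other genes.

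Glycolysis genes were lower, with 13 of 19 falling and 2 rising, the same adjusted over the list alone. The hexokinase gene HK2 fell by 0.85 on the log2 scale, the phosphofructokinase genes PFKP and PFKM by 0.74 and 0.38, and SLC2A1, a glucose transporter and not an enzyme, by 1.13. The median was -0.17 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000203, and adjusted p = 0.311 with an estimated correlation). Of 22 hypoxia targets, 12 fell and 6 rose (13 and 6 adjusted over the list alone). DDIT4 fell by 1.97, the growth factor gene VEGFA by 1.16 and MXI1, which opposes MYC, by 0.87. Their median was -0.19 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0193, and adjusted p = 0.237 with an estimated correlation).

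Ribosome biogenesis genes fell in 11 of 24 cases and rose in 2, the same adjusted over the list alone, with a median of -0.09. Nucleolin (NCL) fell by 0.99 on the log2 scale, WDR43 by 0.65, the helicase gene DDX21 by 0.58 and BOP1 by 0.54. Camera with Benjamini-Hochberg adjustment gave adjusted p = 0.00678, and adjusted p = 0.569 with an estimated correlation. Of 21 stemness genes 8 fell and 1 rose, the same adjusted over the list alone, with a median of -0.06. The transcription factor genes MYC and KLF4 fell by 1.21 and 0.87, and ITGA6 and CD44, which encode adhesion receptors, by 1.14 and 0.70. Of the 11 lists it had the largest adjusted p at the preset correlation, though not at the estimated one (camera with Benjamini-Hochberg adjustment, adjusted p = 0.036, and adjusted p = 0.311 with an estimated correlation). It was lost without control replicate 1 (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.06) and without SHCBP1 shRNA replicate 2 (adjusted p = 0.0566).

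In all, 11 of 39 lists passed camera with its preset correlation of 0.01, 2 higher and 9 lower than other genes (4 higher and 7 lower with spike-in scaling), and 0 passed with an estimated correlation, where 6 had an unadjusted p under 0.05. A larger correlation is not why every list was lost. The matrix protease and hypoxia lists had estimates of -0.032 and -0.032, below the preset value, and did not pass either. The self-contained test fry called 32 lists.

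**Figure D3:**
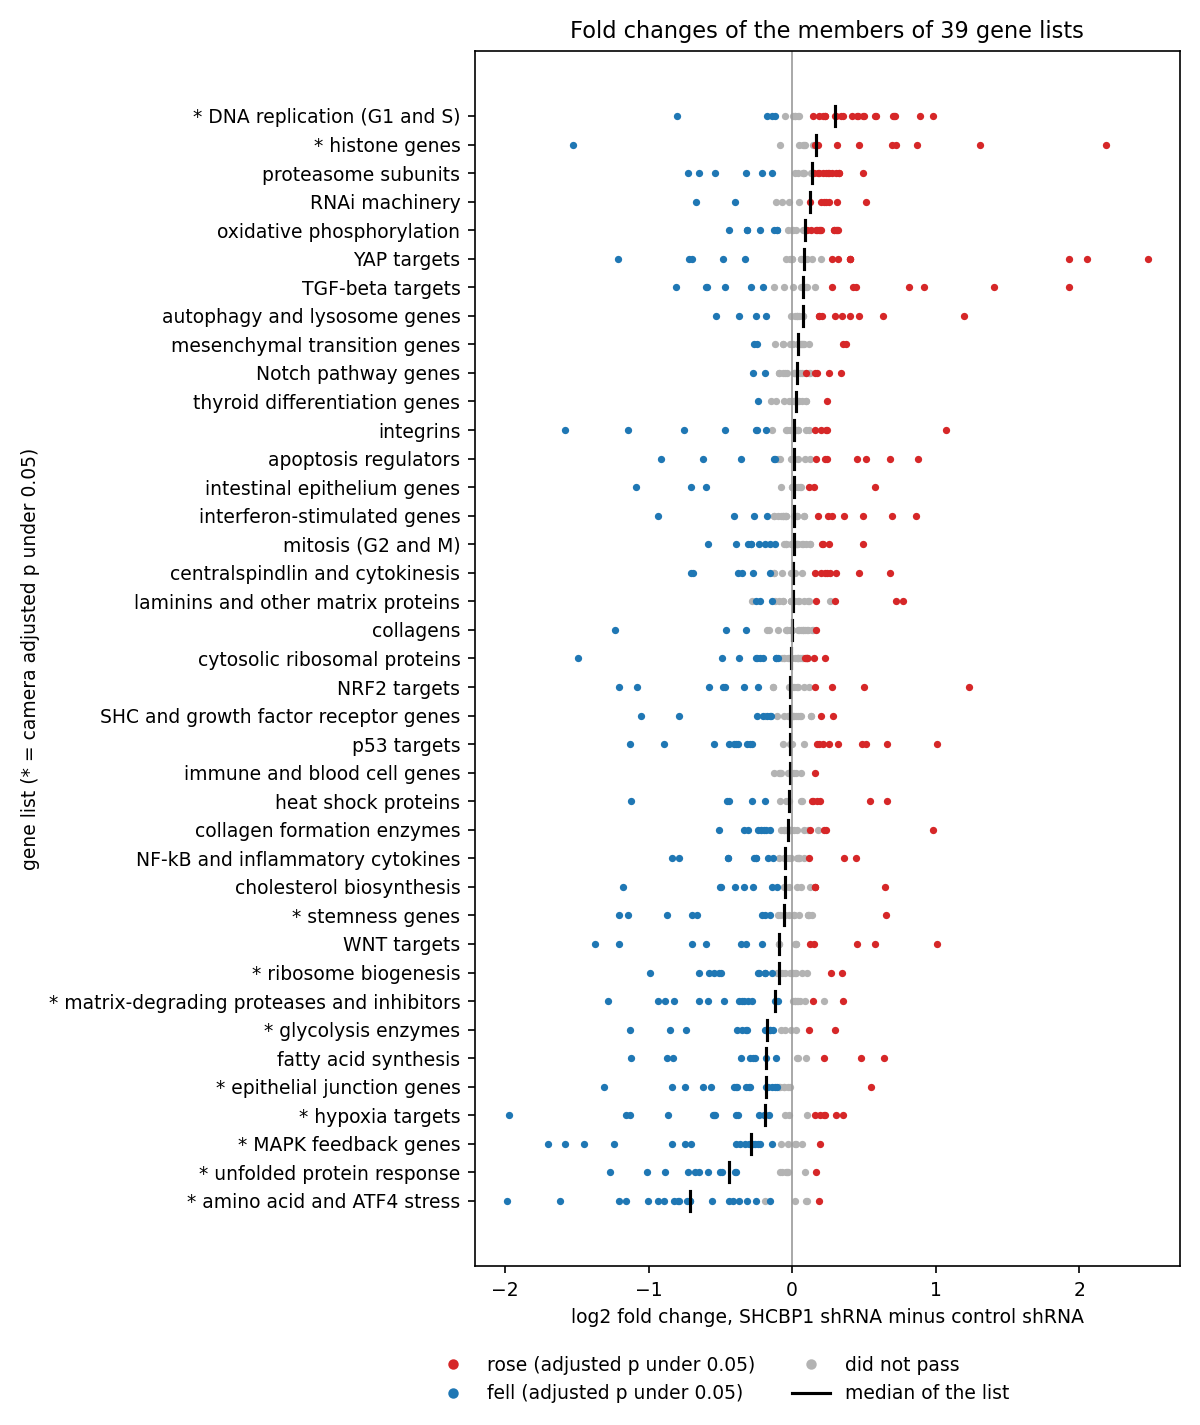
Log2 fold change of each tested member of the 39 gene lists (SHCBP1 shRNA minus control shRNA), coloured by whether it rose, fell or did not pass limma's test, with a bar at each list's median and an asterisk at lists that passed camera. The medians run from -0.71 for the ATF4 list to 0.30 for DNA replication, and under spike-in scaling every value lies 0.43 lower.

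The other 28 lists did not pass camera (Benjamini-Hochberg adjusted p from 0.0934 to 0.97), and many held members that moved in both directions. Among centralspindlin and cytokinesis genes 8 of 20 rose and 6 fell (8 and 8 adjusted over the list alone): the kinesin gene KIF23 rose by 0.47 and CDCA8 by 0.69, while ANLN and CEP55 fell by 0.71 and 0.69. Of 30 mitotic genes 4 rose and 9 fell, the same adjusted over the list alone. NDC80 rose by 0.49, whereas MAD2L1, BUB1B and ASPM fell by 0.58, 0.39 and 0.31. Both lists had a median above 0 (0.0091 and 0.0104) but a mean below 0. Camera's direction for both was lower than other genes, and the median of all tested genes was 0.0223. Of 23 p53 targets 9 rose and 10 fell, the same adjusted over the list alone, with GDF15 and SESN2 falling by 1.13 and 0.89 and TRIAP1 and CCNG1 rising by 1.01 and 0.66. SESN2 is also a target of ATF4. The probe sets of GDF15 ranged from -1.77 to -0.16. Of 21 apoptosis regulators 7 rose and 5 fell (8 and 7 adjusted over the list alone). The pro-apoptotic gene PMAIP1 and the anti-apoptotic gene BCL2L1 fell by 0.91 and 0.62, and the inhibitor gene BIRC2 and the pro-apoptotic gene BAD rose by 0.88 and 0.68.

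YAP targets held the largest rise of any list, ANKRD1 (2.48), with CCN1 (2.05) and CCN2 (1.93), but also the tissue factor gene F3, which fell by 1.21. In that list 8 of 22 rose and 5 fell (10 and 5 adjusted over the list alone), with a median of 0.08. Of 20 TGF-beta targets 7 rose and 6 fell (8 and 6 adjusted over the list alone), and the rises were led by CCN2 and the inhibitor-of-differentiation genes ID3 (1.40), ID2 (0.92) and ID1 (0.82). Of 17 WNT targets 5 rose and 7 fell (5 and 9 adjusted over the list alone): NKD2 fell by 1.37, MYC by 1.21 and CD44 by 0.70, and BAMBI rose by 1.01. Notch pathway genes showed 5 rises and 2 falls among 21 (4 and 2 adjusted over the list alone). DTX3L rose by 0.34 and MAML1 by 0.26, and NRARP and DLL4 fell by 0.28 and 0.19.

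Few collagen genes changed, with 1 of 23 rising and 3 falling, the same adjusted over the list alone. COL4A2 fell by 1.24, COL13A1 by 0.46 and COL18A1 by 0.32, and COL15A1 rose by 0.17. Among integrins 5 of 24 rose and 7 fell, the same adjusted over the list alone. ITGB5, ITGA6 and ITGB1 fell by 1.59, 1.14 and 0.75, and ITGAE rose by 1.07. The collagen and integrin medians (0.0004 and 0.0153) lay above 0 and their means (-0.07 and -0.11) below, and camera's direction for both was lower than other genes. Of 24 laminins and other matrix proteins 4 rose and 3 fell, the same adjusted over the list alone. LAMC1 rose by 0.77, THBS1 by 0.72 and LAMB2 by 0.30, and LAMB1 fell by 0.25. The probe sets of THBS1 ranged from 0.08 to 1.13. The collagen formation enzymes gave 4 rises and 8 falls among 26, the same adjusted over the list alone, with PLOD2 rising by 0.98 and PPIB, P3H4 and P4HB falling by 0.51, 0.33 and 0.31.

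Interferon-stimulated genes rose in 7 of 27 cases and fell in 4, the same adjusted over the list alone. IFIT2, IFIT1 and IFI6 rose by 0.87, 0.69 and 0.50, and HERC5 fell by 0.94. Of 22 genes of NF-kB and inflammatory cytokines 3 rose and 9 fell, the same adjusted over the list alone, with LIF, PTGS2 and CXCL8 falling by 0.83, 0.79 and 0.45 and NFKBIZ rising by 0.45. RNA interference machinery, a set that shRNA itself uses, gave 7 rises and 2 falls among 13, the same adjusted over the list alone. AGO3 and AGO4 rose by 0.51 and 0.31, and TNRC6B and DICER1 fell by 0.67 and 0.40.

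Fatty acid synthesis genes came closest to passing (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0934), with 3 of 15 rising and 9 falling, the same adjusted over the list alone. SCD, FASN and ELOVL6 fell by 1.12, 0.87 and 0.83, and the desaturase gene FADS1 rose by 0.64. Of 18 cholesterol synthesis genes 3 rose and 8 fell (4 and 8 adjusted over the list alone). MSMO1, HSD17B7 and TM7SF2 fell by 1.18, 0.51 and 0.49, and MVK rose by 0.65. Oxidative phosphorylation genes gave 12 rises and 7 falls among 25 (13 and 7 adjusted over the list alone), with UQCRC2 and SDHD rising by 0.32 and 0.31 and NDUFV1 and UQCRC1 falling by 0.44 and 0.31.

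Of 20 NRF2 targets 4 rose and 7 fell, the same adjusted over the list alone. Heme oxygenase (HMOX1) rose by 1.24, while SLC7A11, ABCC3 and TKT fell by 1.20, 1.08 and 0.58. Heat shock genes gave 6 rises and 5 falls among 17 (6 and 6 adjusted over the list alone). CHORDC1 and HSPA4L rose by 0.66 and 0.54, HSPA1B, which has a near-identical copy, fell by 1.13, and HSPD1 fell by 0.45. The probe sets of HSPD1 ranged from -1.01 to 0.75 and its direction turned without probe sets ending in _s_at or _x_at. Autophagy and lysosome genes rose in 9 of 20 cases and fell in 4, the same adjusted over the list alone, with GABARAPL1, MAP1LC3B and ATG12 rising by 1.20, 0.64 and 0.47 and WIPI1 falling by 0.53. Proteasome subunits gave 12 rises and 6 falls among 24 (14 and 6 adjusted over the list alone), although the largest changes were the falls of PSMA7, PSMC3 and PSMB5 (0.73, 0.65 and 0.54 lower) beside a rise of 0.50 for PSMB2. Of 31 cytosolic ribosomal proteins 6 rose and 10 fell (7 and 10 adjusted over the list alone), with RPL30, RPS15, RPL3 and RPL7 falling by 1.49, 0.49, 0.37 and 0.25.

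Of 17 thyroid differentiation genes 1 rose, the transcription factor gene FOXE1 (0.24), and 1 fell, HHEX (-0.24), and adjusted over the list alone 1 rose and 0 fell. Of 16 intestinal epithelium genes 3 rose and 3 fell, the same adjusted over the list alone. KRT20, NOX1 and ASCL2 fell by 1.09, 0.70 and 0.60, and LGR5 rose by 0.58. The median of the intestinal list (0.0123) lay above 0 and its mean (-0.09) below, and its camera direction was lower than other genes. Of 12 immune and blood cell genes 1 rose, ITGAM by 0.16, and 0 fell (0 and 0 adjusted over the list alone).

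Some of these calls were lost with fewer arrays, with other probe sets or with fewer genes tested. Leaving out control replicate 1 ended the calls of SNAI1 (-0.20), LAMB2 (0.24), HHEX (-0.25) and ITGAM (0.14), and leaving out control replicate 2 those of SNAI2 (0.38), SNAI1 (-0.27), LAMB2 (0.29) and HHEX (-0.18). Without control replicate 3 SNAI2 no longer passed (0.25). The calls of SNAI2 (0.33), SNAI1 (-0.24) and ITGAM (0.13) ended without SHCBP1 shRNA replicate 1, and those of SNAI2 (0.29), SNAI1 (-0.22) and HHEX (-0.20) without replicate 2 of that group. Without its replicate 3, LAMB2 (0.23) and HHEX (-0.21) no longer passed. Using only plain _at probe sets, an alternative chosen after seeing the data, ended the calls of MAD2L1, ITGB1, MSMO1 and AGO3. Their signs turned, to 0.08, 0.03, 0.10 and -0.08. E2F2 (0.22), MAML1 (0.04) and RPL3 (-0.01) no longer passed either. Nor did SNAI1 (-0.26) and HHEX (-0.24), but their only probe set and their values stayed the same. Their calls ended because moderation and adjustment ran over fewer genes (8324). The ribosome biogenesis, histone and stemness lists no longer passed under that alternative. The apoptosis and TGF-beta lists turned to means of -0.23 and -0.29 and passed as lower (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0116 and 0.0401). The NF-kB and inflammatory cytokine list passed as lower too (mean -0.21, adjusted p = 0.0115). These calls used the preset correlation of 0.01 only. The apoptosis and TGF-beta means also covered fewer members, because BIRC2, BAD, ID1, ID2, ID3 and CCN2 have no plain _at probe set. Leaving out _s_at and _x_at probe sets, also chosen after seeing the data, ended the calls of ITGAM (0.13), MAML1 (0.04) and RPL3 (-0.01) and that of the stemness list (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.128).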

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

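The tests of the poly-A controls in this part were chosen only after the result was seen, and so was the scaling to them.

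Control probe sets that enter no gene comparison are given here where all 3 arrays of one group lay above all 3 of the other, as 10% would by chance, which leaves out cre (0.02 log2 higher) and the background probe sets (0.02 log2 higher). The poly-A spike-in controls, bacterial transcripts added before labelling, were higher with SHCBP1 shRNA by 0.43 ± 0.04 log2 (SE, n = 3): dap by 0.52, lys by 0.30, phe by 0.39 and thr by 0.54. The bioB, bioC and bioD hybridization controls, added later, were higher by 0.15 ± 0.03 (SE), 0.089 and 0.043, but RMA's quantile step would remove an array-wide difference in brightness from all of these, so the comparison says nothing for or against one. More spike-in RNA relative to sample RNA at labelling would raise each of the 4 transcripts beyond bioB. Judged by the smallest shift, 0.30 ± 0.06 (SE) for lys, this was not settled against the 0.15 of bioB. Further above bioB lay dap (0.52 ± 0.01), phe (0.39 ± 0.07) and thr (0.54 ± 0.05, all SE). The bioB value went through the same quantile step, so it is only a rough mark. More spike-in RNA and a lower content of polyadenylated RNA in the SHCBP1 shRNA samples, a biological explanation left untested, cannot be told apart. The labels give no spike-in amounts or cell numbers.

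The 28S ribosomal RNA probe sets were higher with SHCBP1 shRNA by 2.80 log2 at the 5′ end, 1.56 in the middle and 0.30 at the 3′ end. The 18S ribosomal RNA probe sets changed by -0.58 log2 at the 3′ end and -0.24 at the 5′ end. The ACTB control probe sets were higher by 0.20 log2 (3′) and 0.28 (5′), and those of GAPDH by 0.040 and 0.046.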

How the results depend on the processing

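Scaling to the spike-in controls, robust moderation and both selections of probe sets by name were chosen only after the result was seen. Quantile normalization again, centring of arrays, array weights and leaving out single arrays kept all 4 main results within 1.5 times or on their side of the threshold. For changes of at least 2-fold this holds for the total only. Quantile normalization again gave 93 rises and 119 falls, against 57 and 164. On centred values that step evens the tails by construction, so it is a weak check of these counts. Leaving out single arrays gave 6655 to 6840 genes, 217 to 227 of at least 2-fold, 10 to 11 lists and an SHCBP1 log2 fold change of -1.59 to -1.47. Counts of genes that differed were 1882 (104 of at least 2-fold) with only plain _at probe sets, where 8324 genes were tested, 17325 (848) counting each probe set on its own, and 16709 (694) with spike-in scaling, which moves every gene by -0.43 log2. Lists past the threshold numbered 0 with an estimated correlation and 32 with fry, which does not compare a list with other genes. With only _at probe sets, 59 of the 164 named genes, SHCBP1 included, could be tested. The log2 fold change of HSPD1 reversed (0.75, also 0.75 without _s_at and _x_at probe sets). Those of MAD2L1 (0.083), ITGB1 (0.035), MSMO1 (0.098) and AGO3 (-0.078) changed sign but did not pass limma's test. For ITGB1 and AGO3 that setting left a single probe set, which did not pass on its own. Their other probe sets fell by 0.76 to 1.10 (ITGB1) and rose by 0.63 to 0.80 (AGO3). Why probe sets of one gene differ was not tested. The apoptosis (-0.23) and TGF-beta (-0.29) list means also reversed, but over fewer members. BIRC2, BAD, ID1, ID2, ID3 and CCN2 have no plain _at probe set and dropped out. Of 163 named genes other than SHCBP1, 163 kept direction and call under quantile normalization again and centring, 162 with array weights (SNAI2 did not pass) and 159 to 162 without single arrays. The replicate numbers do not pair the arrays (correlations 0.018, -0.046 and 0.067). With the replicate block 7092 genes, 221 of at least 2-fold and 10 lists passed, SHCBP1 stayed at -1.54, the stemness list did not pass (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0554) and SNAI1 did not pass. The filters on dim genes, cyclic loess and a variance trend were not run because centred values hold no signal over background, which also keeps dim genes among those tested.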

Other observations

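The gene lists in the next 2 paragraphs and the comparison of intestinal with thyroid genes were chosen only after the result was seen, as were the spike-in and _at settings. The other tests were planned.

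The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids and include known ATF4 targets, mostly fell: 16 of 19 were lower and 3 higher, with a median log2 fold change of -0.40. EPRS1 fell by 0.88, WARS1 by 0.79 and AARS1 by 0.74, and FARSB, HARS1 and RARS1 rose by 0.12, 0.12 and 0.18. Without WARS1 and SARS1, which are also in the ATF4 list and prompted this one, 14 of 17 fell and 3 rose (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 2.92e-06, and adjusted p = 0.0891 with an estimated correlation). Their mitochondrial counterparts gave 4 rises and 5 falls among 16, with a median of 0.01, though TARS2 and RARS2 fell by 1.36 and 0.86. The direction against other genes was lower but did not pass (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.342). Whether the 2 sets differ was not tested.

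Of 16 known targets of BMP signalling 10 rose and 0 fell, with a median of 0.33, but 7 of the 16 prompted the list by their changes or their place in the TGF-beta list. MSX1 rose by 1.87, ID3 by 1.40, BAMBI by 1.01 and MSX2 by 0.61. Without those 7, 4 of 9 rose and 0 fell, with a median of 0.08, and the list did not pass (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.217). Genes of UDP-N-acetylglucosamine synthesis (1 of 6 rose, 3 fell) and of purine synthesis (3 of 11 rose, 6 fell) did not pass even with the genes that prompted them (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 0.0509 and 0.0551). In the purine list PAICS fell by 1.82 and IMPDH2 by 0.60, while PRPS1 rose by 0.49.

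The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 of 10 splits, the real one, gave as many genes (7440, against 0 at most in the others), 1 of 10 as many genes of at least 2-fold (221 against 0), and 1 of 10 as many lists (11 against 5). Each of the other 9 splits mixes the real groups, which puts the difference between them into the spread within a group. Counts near 0 were to be foreseen there, so the gene counts decide nothing about chance. The other 9 splits gave 1 to 5 lists by camera with its preset correlation. They still hold part of the real difference, so that range is not a chance rate.

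Falls of at least 2-fold outnumbered rises 164 to 57, a ratio of 2.88. Probe sets shared between genes or transcripts would bring the ratio to 1 or under once they are left out. With only plain _at probe sets it was 1.74 (66 to 38), which argues against them as the whole cause for the 8324 genes tested there. That setting covers fewer genes, so the step from 2.88 to 1.74 does not measure what shared probe sets contribute. Without _s_at and _x_at probe sets 153 genes fell and 60 rose by at least 2-fold. The ratio depends on the scaling, from 1.28 with quantile normalization again (119 to 93) to 39.8 with spike-in scaling (677 to 17). Quantile normalization of centred values evens the tails by construction, so scaling and an effect of the SHCBP1 shRNA on more genes downward cannot be told apart here. A measure of RNA per cell would be needed to set the scale.

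The extraction text names a colorectal line, and intestinal genes passed the threshold more often (6 of 16) than thyroid genes (2 of 17), at 37.5% and 11.8% against 41% of all tested genes. The difference between the lists did not pass a two-sided Fisher exact test (p = 0.118), and the intestinal share was not above that of all genes. A hypothesis that the RNA came from a colorectal line, whose intestinal genes could change more often, stays open: changes were larger in the intestinal list (SD of log2 fold changes 0.39, with KRT20 at -1.09) than in the thyroid one (SD 0.11), a difference not tested. Of the intestinal genes, AXIN2, LGR5 and ASCL2 are also in the WNT list. The centred values hold no expression levels, so which line gave the RNA cannot be told apart from these arrays.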
